A study of Homo sapiens with 72 samples.

How the data were processed

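The values analysed were raw read counts per gene, deposited by the authors as a table of counts for each of 4 batches. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0, aligned to GRCh38 with STAR 2.6.0 and counted with featureCounts, whose version is not given. The tables held 25372, 25372, 33121 and 60671 gene entries in batches 1 to 4. Symbols were brought to their current form, and the 23258 symbols common to the 4 tables were kept. These held 76.65% to 99.51% of the counts of a library. Tables of normalised counts (CPM) were deposited too and not used, and 1 column of counts that matched no labelled sample was left out. CPM given in the report are counts scaled to the total over the common genes, with no TMM factor. Exceptions are the ranges of FTH1 over the libraries of a batch and the levels of its pseudogenes, which were scaled to all counts of a library.

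Libraries that share a batch, a group and a replicate number differ by a letter in the labels, and were treated as repeated libraries of the same biological replicate and summed. The 49 pairs of such libraries had a chi-square per gene of 1.039 to 24.144 (median 1.474), and 0 pairs were identical. Letter B of T47D from co-culture with HS27a in batch 3 stood apart from its companions (23.083 and 24.144, against 2.712 between letters A and C). Conditioned-medium groups have 1 biological replicate, so their tests take the spread from the other groups of the line and assume that the lone sample varies like them. Counting intervals of folds and floors cover counting error only, and a floor is 3 counts over a whole group. Intervals of shares and list medians are bootstraps over genes, and that of the mean of the interferon list carries the spread between cultures.

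Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, robust quasi-likelihood fits with a term for batch, all groups of a line in 1 fit, two-sided F tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and rose or fell is used of called genes. The SE of a log2 fold change comes from the same fit. The comparisons, lists, rule for naming genes and alternatives were chosen before the data were examined, except for alternatives with batch 3 alone, with letter B left out and for the differences between partners and between lines. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom with a random block for the biological replicate) served as alternatives, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for the remaining steps.

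The share of partner RNA in a co-cultured fraction was the median, over genes with at least 20 CPM in the partner and at most 1% of that in the own line, of the position of the fraction between the own monoculture and the partner fraction of the same co-culture and batch (the partner monoculture where the batch has no such fraction). Genes with a gap under 5 CPM between these were not used, and 500 bootstrap draws over genes gave the 95% interval. Each co-culture was fitted a second time with an offset per gene for the mixture that this share predicts (prior 0.5 CPM), called the allowance. Known shares of 0, 1, 5 and 20% mixed into monocultures came back as 0%, 0.670% to 0.949%, 4.497% to 4.990% and 18.396% to 19.929%.

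Gene lists were tested with camera on the edgeR fits, at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists within a comparison. A list needed at least 5 measured members. With the preset correlation 3 to 18 lists per comparison were called, and with an estimated correlation 0 of 26 were called in each of the 13 comparisons. Lists of leukocyte and endothelial markers had fewer than 5 measured members in every comparison and were not tested. A list of mitochondrially encoded genes was not read across batches, since the tables do not hold the same entries for them.

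Genes were named by a fixed rule. A gene needed a symbol that is no clone name, a call with a log2 fold change of at least 1 in size, at least 5 CPM in the higher group and the same direction in every batch with both groups. For co-cultures the call, the direction and the size had to hold with and without the allowance, and partner RNA had to make up under 25% of the level. By size, up to 8 genes each way were taken for co-cultured cancer cells and for HS5 against HS27a, 6 for co-cultured stromal cells and 5 for conditioned medium. Up to 8 called iron genes by smallest p, up to 4 members of each list described, and TFRC, FTH1, FTL, SLC40A1, LCN2 and ESR1 were added whether called or not, the last in cancer lines. EPCAM, KRT8, VIM and COL1A1 served as a check of the separation. The report names a selection from these.

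Counts were simulated with up to 200 changed genes, drawn only from genes with a mean of at least 20 counts. The shares of changes that edgeR called therefore do not hold for genes with fewer counts. Of changes of 2-fold and 4-fold it recovered 65% and 97% in MCF7 with HS5, 77% and 94% in MCF7 with HS27a, 70% and 97% in T47D with HS5, and 75% and 99% in T47D with HS27a. For conditioned medium these were 30% and 81% (MCF7, HS5), 10% and 86% (MCF7, HS27a), 54% and 91% (T47D, HS5), and 55% and 91% (T47D, HS27a). For stromal cells these were 89% and 100% in HS5 with MCF7 and in HS27a with MCF7, 85% and 99% in HS5 with T47D, 71% and 94% in HS27a with T47D, and 20% and 86% for HS5 against HS27a. For the difference between the cancer lines these were 17% and 71%. Wrong calls made up 3% to 14.3% of calls. With partner RNA mixed in, wrong calls made up 10.9% to 74.9% of calls without the allowance and 4.6% to 11.4% with it. The mixture put in was the same that the allowance removed, with no error in the share or in the partner levels. The lower share of wrong calls with the allowance was thus fixed in advance and does not test it against such errors. DESeq2 recovered 62% and 97% in MCF7 with HS5 (10.7% wrong) and 47% and 86% in T47D with HS5 (0.7% wrong), and limma voom had 40.7% and 61.3% wrong calls there. A raised list was called in 13 of 13 simulations, and 0 of 26 unchanged lists were called in each.

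Whether equal replicate numbers in the labels pair the samples was read from correlations of deviations from group means, with no batch effect removed. A sample matched the control of its own number best in 3 of 3 cases for both MCF7 co-cultures, HS5 with MCF7, HS27a with MCF7 and HS5 against HS27a, in 1 of 3 for HS5 with T47D, T47D with HS27a and HS27a with T47D, and in 0 of 2 for T47D with HS5. For the MCF7 co-cultures and HS5 against HS27a, the number and the batch are the same. There batch effects alone can give such matches, and the batch term is also the block by number. Where they differ, number 2 correlated at -0.78 in T47D with HS5, -0.728 in T47D with HS27a and -0.56 in HS27a with T47D. Each matched the control of its own batch best. Number 3 of HS5 and of HS27a with MCF7 had no control in its batch and matched its own number (0.385 and 0.333). For the other comparisons the block by number was an alternative, and calls lost with it are no test of pairing.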

Results

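Read counts per gene were collected by RNA sequencing from 72 libraries of 4 established human cell lines. MCF7 and T47D are estrogen receptor-positive breast cancer lines, and HS5 and HS27a are stromal lines from bone marrow. The 16 groups were the monoculture of each line, each line after co-culture with each partner of the other kind, and each cancer line kept in medium conditioned by each stromal line. Per the labels, co-cultures were seeded with 10% cancer and 90% stromal cells, kept for 24 h in full medium and for 48 h in medium with 1% serum and 10 nM estradiol, and parted with beads against EpCAM, an epithelial surface protein. Libraries of the same biological replicate were summed, which gave 39 biological replicates in 4 labelled batches. Each monoculture and each co-cultured fraction had 3 biological replicates, except T47D from co-culture with HS5, which had 2. Each conditioned-medium group had 1 biological replicate of 3 libraries in batch 3. Total counts per library ran from 1272821 to 5840554 (median 2923408.5), with 7 libraries in batch 1, 26 in batch 2, 30 in batch 3 and 9 in batch 4.

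The study's title names iron and resistance to drugs induced by mesenchymal stem cells, so genes of iron handling were followed in every comparison. On GRCh38, TFRC, which encodes the transferrin receptor for iron uptake, lies on chromosome 3 from 196049284 to 196082090. The ferritin genes FTH1 and FTL, which encode iron storage subunits, lie on chromosome 11 from 61964285 to 61967634 and on chromosome 19 from 48965309 to 48966879. SLC40A1, which encodes the iron exporter ferroportin, lies on chromosome 2 from 189560590 to 189580786, and CP, which encodes the copper oxidase ceruloplasmin, on chromosome 3 from 149162414 to 149221829. LCN2, which encodes the siderophore-binding protein lipocalin, lies on chromosome 9 from 128149453 to 128153453, and ESR1, which encodes the estrogen receptor, on chromosome 6 from 151656672 to 152129619.

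RNA of the partner line was present in the separated fractions, most of all in MCF7. The stromal gene VIM, for the filament protein vimentin, was at 0.584 ± 0.347 CPM in MCF7 monoculture, 950 ± 778 CPM in MCF7 from co-culture with HS5 and 6313 ± 1933 CPM in HS5 monoculture (SD, n = 3 each). The epithelial gene EPCAM was at 570 ± 80.2 CPM in MCF7 monoculture, 544 ± 58.9 CPM in MCF7 from co-culture with HS5 and 1.87 ± 1.80 CPM in HS5 monoculture. HS5 RNA made up 24.9% of the MCF7 fraction in batch 1, 17.3% in batch 2 and 0.820% in batch 3. HS27a RNA made up 12.8%, 9.16% and 0.266% of the MCF7 fraction in the same batches. In T47D the partner share ran from 0.609% to 3.24% with HS5 and from 0.534% to 2.27% with HS27a. Cancer RNA made up at most 4.36% of HS5 and 5.69% of HS27a after co-culture with MCF7, and at most 1.19% and 0.002% after co-culture with T47D. Each co-culture was therefore tested with and without an allowance for partner RNA, and the log2 fold changes of co-cultured cells below (± SE) include the allowance. CPM, log2 ratios of single genes within a batch and folds taken from counts do not include it.

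**Figure D1:**
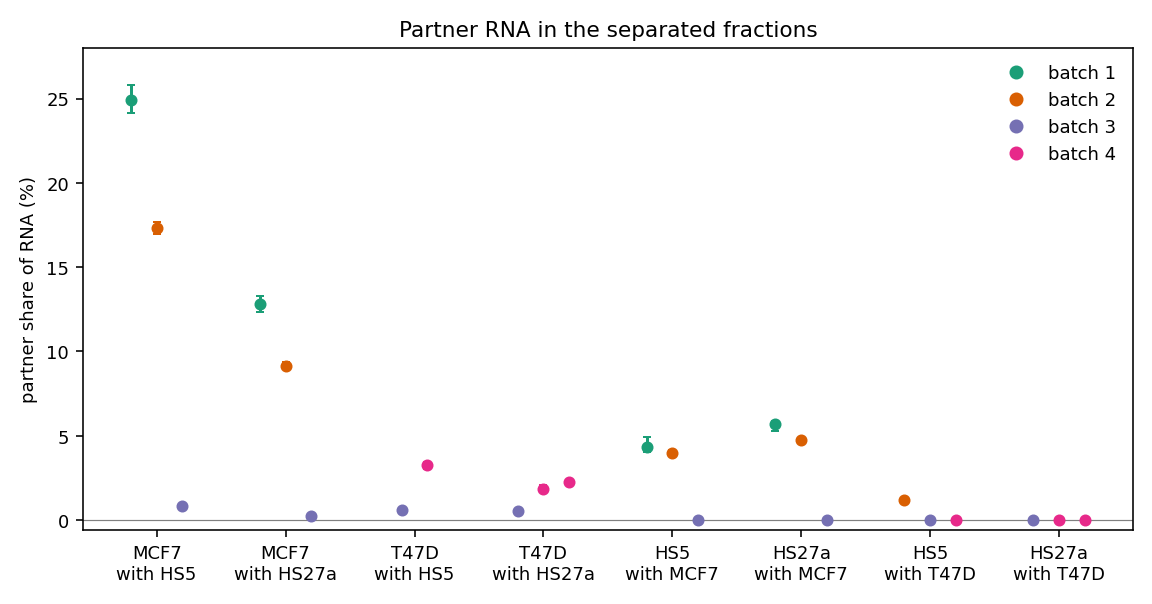
Share of partner RNA in percent (y axis) in each separated fraction (x axis, line and partner), 1 point per biological replicate with its 95% bootstrap interval over genes, coloured by batch. The MCF7 fractions of batches 1 and 2 held 9.16% to 24.9% partner RNA, and those of batch 3 held 0.266% and 0.820%.

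MCF7 fractions from co-culture with HS5 had lower levels of the estrogen receptor and of part of the estrogen response, and higher levels of genes of stress, sterol synthesis and acute-phase signalling (3 against 3 biological replicates). ESR1 fell by 1.26 ± 0.14 on the log2 scale, from 746.5 ± 55.5 CPM to 273 ± 64.7 CPM (SD), and it was lower in each of the 3 batches (log2 ratios -1.96, -1.12 and -1.35, before the allowance and so with dilution by HS5 RNA included). TXNIP, an arrestin-like inhibitor of thioredoxin, fell by 4.36 ± 0.17, from 592 ± 91.2 CPM to 25.9 ± 5.36 CPM, and the kallikrein protease gene KLK11 fell by 4.04 ± 0.36. The adenylyl cyclase gene ADCY5 rose by 4.59 ± 0.26. S100A7A, an S100 calcium-binding protein gene with no counts in monoculture, was at least 18.8-fold higher.

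Of 32 measured genes of iron handling in MCF7 with HS5, 3 rose, 1 fell and 28 did not pass the test (2 up and 1 down adjusted over the list alone). The list was called up by camera with a preset correlation (p = 0.0306), and not otherwise (adjusted p = 0.369 with an estimated correlation). STEAP4, a metalloreductase gene, rose by 4.35 ± 0.57, CP by 4.41 ± 0.75 and ISCU, a scaffold of iron-sulfur cluster assembly, by 0.46 ± 0.15. NCOA4, the receptor that carries ferritin to lysosomes, fell by 0.52 ± 0.14. TFRC (log2 fold change 0.38 ± 0.13, adjusted p = 0.0537), FTH1 (0.15 ± 0.12, adjusted p = 0.415), FTL (0.06 ± 0.13, adjusted p = 0.803) and LCN2 (5.14 ± 1.27, adjusted p = 0.0707) did not pass, though LCN2 was called without co-culture replicate 3 (4.40). In the joint fit of both cancer lines, TFRC (0.368, adjusted p = 0.0368) and LCN2 (5.116, adjusted p = 0.0139) were called up in MCF7, so their calls depend on the fit. SLC40A1 was at or under the floor of 3 counts in both groups. The calls of NCOA4 and ISCU each ended when single replicates were left out, for ISCU whichever of the 6 was left out, and for NCOA4 without MCF7 monoculture replicate 1 (-0.51) or 3 (-0.47) or co-culture replicate 2 (-0.52) or 3 (-0.45). In the separate set of genes for glutathione, NRF2 and ferroptosis, 5 of 23 rose and none fell (6 up adjusted over the list alone, camera p = 0.00229, adjusted p = 0.341 with an estimated correlation), among them the cystine carrier SLC7A11 at 3.14 ± 0.52 (call lost without MCF7 monoculture replicate 2, 2.90) and the ferroptosis suppressor AIFM2 at 1.17 ± 0.18.

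Among the other groups in MCF7 with HS5, 14 of 26 genes of ER stress and the amino acid response rose and none fell (18 up adjusted over the list alone), with MANF at 1.14 ± 0.15, PDIA4 at 0.98 ± 0.13 and CEBPG at 1.17 ± 0.16. Its camera p was 2.14e-11, and adjusted p = 0.341 with an estimated correlation. In cholesterol synthesis 11 of 24 genes rose and 1 fell (14 and 1 adjusted over the list alone), with MVD at 1.38 ± 0.14 and HMGCS1 at 0.77 ± 0.12. Its camera p was 1.14e-07, and adjusted p = 0.296 with an estimated correlation. In the STAT3 and acute-phase list 7 of 22 rose and none fell (10 up and 1 down adjusted over the list alone, camera p = 1.52e-05, adjusted p = 0.341 with an estimated correlation), including the transcription factor gene CEBPB at 1.62 ± 0.18 and the receptor gene OSMR at 1.40 ± 0.23. In the NF-kB list 9 of 26 rose and none fell (9 up adjusted over the list alone, camera p = 1.14e-05, adjusted p = 0.383 with an estimated correlation). Of 40 genes of the estrogen response 14 fell and 3 rose (16 and 5 adjusted over the list alone), with MYB falling by 1.58 ± 0.17 and MYBL1 by 1.48 ± 0.16. The camera p was 1.33e-05, and adjusted p = 0.341 with an estimated correlation. Of 33 genes of the cell cycle 12 fell and none rose (14 down adjusted over the list alone, camera p = 0.000519, adjusted p = 0.52 with an estimated correlation), among them the replication helicase genes MCM3 (fell by 0.87 ± 0.17) and MCM4 (fell by 0.75 ± 0.13). The keratin gene KRT8 fell by 1.28 ± 0.18, and 10 of 28 epithelial markers fell and 2 rose (11 and 3 adjusted over the list alone, camera p = 0.00228, adjusted p = 0.341 with an estimated correlation). Of 28 stromal markers 7 rose (9 adjusted over the list alone, camera p = 0.0383, adjusted p = 0.535 with an estimated correlation). HS5 RNA made up 24.9% and 17.3% of these fractions in batches 1 and 2. Since stromal markers rose even with the allowance, remaining HS5 RNA was not excluded as a source of the NF-kB and acute-phase calls.

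For MCF7 with HS5, edgeR called 2772 of 12903 genes without the allowance (1644 up, 1128 down) and 2049 with it (1116 up, 933 down). With the allowance the count was 161 without a batch term, and 1100 without MCF7 monoculture replicate 1, 1251 without replicate 2 and 1186 without replicate 3. It was 1205 without co-culture replicate 2 and 1290 without replicate 3.

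MCF7 cells from co-culture with HS27a had higher levels of sterol synthesis genes (3 against 3 biological replicates). ADCY5 rose by 4.12 ± 0.26. CYP26A1, which encodes a retinoic acid hydroxylase, rose by 3.95 ± 0.49. CDSN, for the desmosomal protein corneodesmosin, fell by 5.17 ± 0.46, from 15.4 ± 7.46 CPM to 0.345 ± 0.143 CPM, and PKP1, for a desmosomal plakophilin, by 3.10 ± 0.34. In cholesterol synthesis 8 of 24 genes rose and none fell (15 up adjusted over the list alone), among them HMGCS1 at 0.82 ± 0.12 and DHCR24 at 0.77 ± 0.14, whose call ended without MCF7 monoculture replicate 1 (0.61). The MVD call ended without co-culture replicate 1 (0.63) or monoculture replicate 2 (0.64). The DHCR7 call ended without co-culture replicate 1 (0.56) or 2 (0.63) or monoculture replicate 2 (0.46) or 3 (0.63). The camera p of the list was 1.76e-10, and adjusted p = 0.116 with an estimated correlation.

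In the iron handling list of MCF7 with HS27a, 2 of 32 genes rose and none fell (2 up adjusted over the list alone, camera p = 0.114, adjusted p = 0.587 with an estimated correlation). These were CP, at 4.21 ± 0.74, and TFRC, at 0.46 ± 0.13 (adjusted p = 0.0428). CP was at 13.962 and 8.458 CPM in the co-cultures of batches 1 and 2, where the HS27a share was 12.8% and 9.16%. In batch 3, where the share was 0.266%, CP was at 0.51 CPM against 0.314 CPM in monoculture. Its rise was thus seen only where HS27a RNA was abundant. The TFRC call ended whichever of the 6 replicates was left out, with values from 0.34 without MCF7 monoculture replicate 1 to 0.54 without monoculture replicate 3, and the CP call ended without co-culture replicate 2 (3.80). FTH1 (0.14 ± 0.12, adjusted p = 0.58), FTL (-0.03 ± 0.13, adjusted p = 0.934), LCN2 (4.03 ± 1.23, adjusted p = 0.182) and ESR1 (-0.36 ± 0.14, adjusted p = 0.147) did not pass, though LCN2 was called without co-culture replicate 3 (4.54). LCN2 was at 487 and 200 CPM in the co-cultures of batches 1 and 2, against 28.3 and 8.03 CPM in monoculture. In batch 3, with little HS27a RNA, it was at 1.53 CPM against 0.627 CPM. SLC40A1 had no counts in monoculture and was at least 8.03-fold higher before the allowance, where partner RNA accounted for more than its whole level. Of 40 genes of the estrogen response 6 fell and 2 rose (14 and 5 adjusted over the list alone, camera p = 0.000775, adjusted p = 0.504 with an estimated correlation), including RAB31, which fell by 1.00 ± 0.13, and CXCL12, a chemokine gene that fell by 1.53 ± 0.26 (call lost without co-culture replicate 2, -1.51). Stromal markers rose in 6 of 28 cases (11 adjusted over the list alone, camera p = 0.000933, adjusted p = 0.504 with an estimated correlation), beside the HS27a shares given above. By edgeR the counts were 944 genes without the allowance (592 up, 352 down) and 667 with it (314 up, 353 down). With the allowance the count was 3 without a batch term, 168, 398 and 311 without MCF7 monoculture replicates 1, 2 and 3, and 220 and 288 without co-culture replicates 1 and 2.

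The direct contrast of the stromal partners in MCF7, with the allowance, called 498 genes (293 higher with HS5, 205 higher with HS27a). TXNIP was lower with HS5 than with HS27a (log2 difference -2.55 ± 0.16), and so was ESR1 (-0.91 ± 0.14). That count was 2 without a batch term.

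T47D cells from co-culture with HS5 had higher levels of secreted acute-phase genes and a lower level of the estrogen receptor (2 against 3 biological replicates). T47D monoculture replicate 1 was the only T47D sample of batch 2. With the batch term it adds nothing to any T47D log2 fold change or its spread, though the CPM means of monoculture include it. FGB, which encodes a fibrinogen chain, was 1830 times its monoculture level (95% counting interval 506 to 15100) and reached 232 ± 66.2 CPM. LBP, which encodes the lipopolysaccharide-binding protein, was 232 times its monoculture level (63.9 to 1920), and the complement gene C3 rose by 6.02 ± 0.31, from 2.69 ± 1.72 CPM to 212 ± 71.1 CPM. ESR1 fell by 1.99 ± 0.15, from 239 ± 33.7 CPM to 60.8 ± 8.84 CPM, with log2 ratios of -2.02 in batch 3 and -2.11 in batch 4. LRRN3, a neuronal leucine-rich repeat gene, fell by 5.32 ± 0.23, from 145 ± 25.2 CPM to 3.27 ± 1.34 CPM. HSPB1, a small heat shock protein gene, fell by 2.15 ± 0.12.

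Of 35 measured genes of iron handling in T47D with HS5, 12 rose, 4 fell and 19 did not pass (13 up and 4 down adjusted over the list alone). Its camera p was 0.000165, and adjusted p = 0.108 with an estimated correlation. CP rose by 8.89 ± 0.47, from 0.385 ± 0.429 CPM to 88.6 ± 28.5 CPM, and LCN2 by 12.62 ± 0.70, from 2.78 ± 4.41 CPM to 1495 ± 1364 CPM. The LCN2 mean of monoculture comes mostly from batch 2 (7.864 CPM), which held no co-cultured T47D fraction. LCN2 was at 0.0 CPM in the monoculture of batch 3 and 0.464 CPM in that of batch 4, so the size of its fold is poorly fixed. The metalloreductase genes STEAP1, STEAP2 and STEAP4 rose by 2.35 ± 0.18, 1.80 ± 0.17 and 2.73 ± 0.29, and SLC25A37, which encodes the mitochondrial iron carrier mitoferrin, by 1.14 ± 0.17. FTL rose by 1.11 ± 0.15 and FTH1 by 1.71 ± 0.19. TFRC fell by 0.59 ± 0.12, from 1375 ± 210.5 CPM to 945 ± 158 CPM, and SLC40A1 fell by 0.99 ± 0.20, from 435 ± 106 CPM to 186 ± 60.9 CPM. FTH1 had 0.0 to 2.7 CPM in every library of batch 4, so its change rests on batch 3 (log2 ratio 1.66), and its call ended without T47D monoculture replicate 2 (5.73). FTH1 changed sign (-4.43) with the replicate number of the labels as a block in place of batch. The SLC40A1 call ended without T47D monoculture replicate 2 (-0.73).

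**Figure D2:**
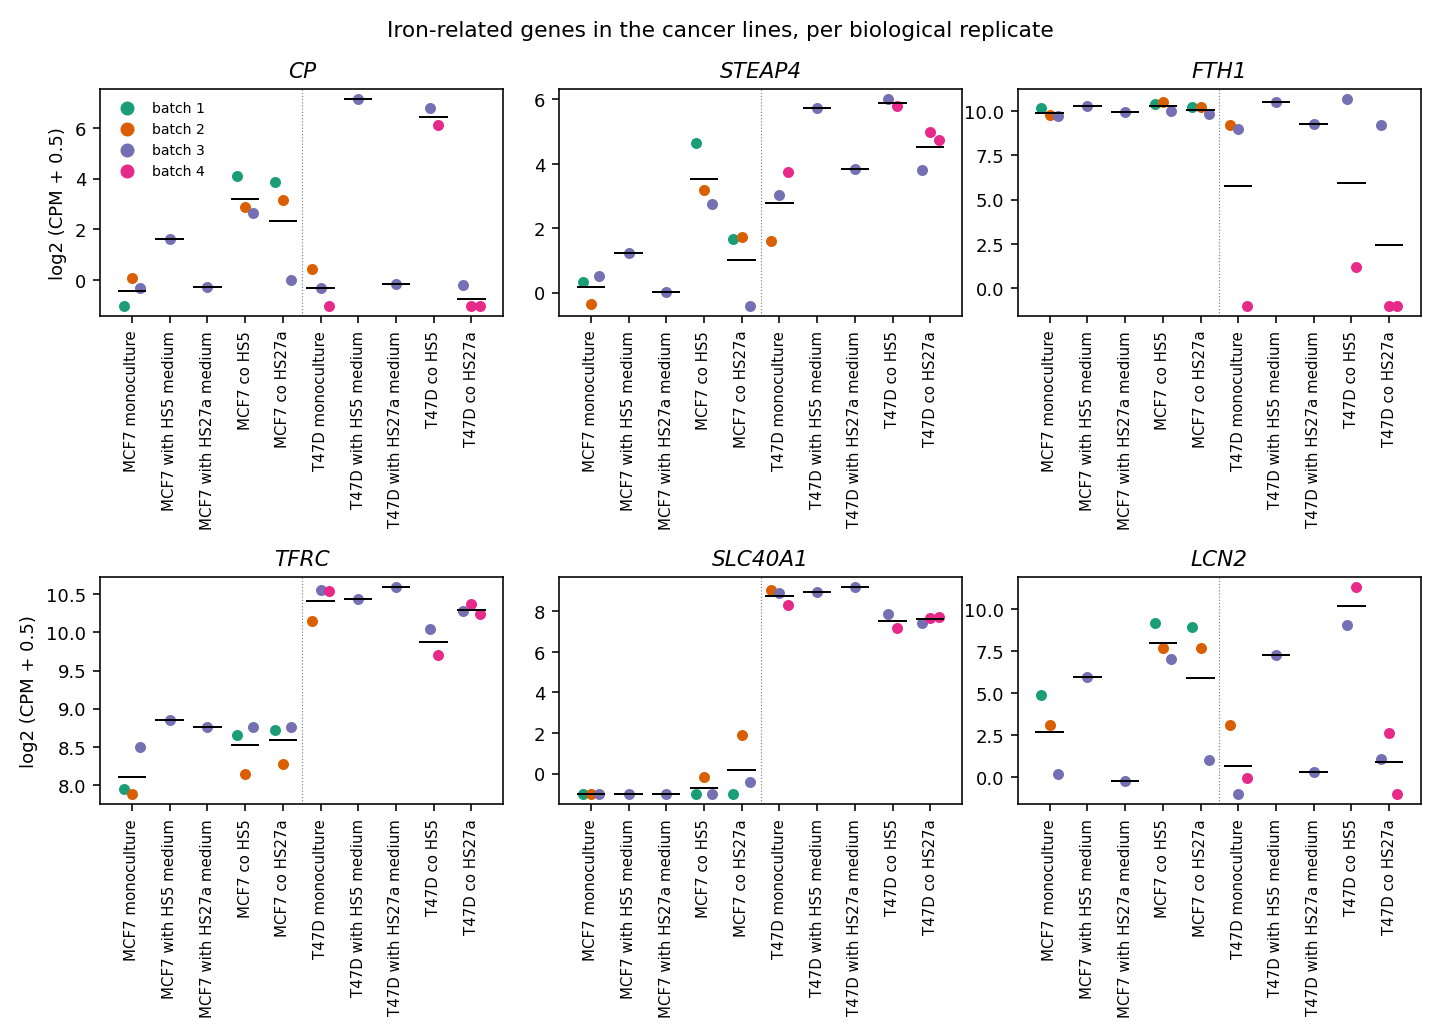
Levels of 6 iron-related genes as log2 of CPM plus 0.5 (y axis) in the MCF7 and T47D groups (x axis; co stands for co-culture, medium for conditioned medium), 1 point per biological replicate coloured by batch, with a bar at the group mean. In T47D, CP and LCN2 were highest with HS5, SLC40A1 was lower in both co-cultures, and FTH1 lay at 0.0 to 1.74 CPM in batch 4.

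Among the other groups in T47D with HS5, 17 of 26 genes of ER stress and the amino acid response rose and none fell (23 up adjusted over the list alone), with DDIT3 at 2.82 ± 0.21, TRIB3 at 2.04 ± 0.18 and SESN2 at 1.76 ± 0.16. The camera p was 2.27e-21, and adjusted p = 0.108 with an estimated correlation. In the STAT3 and acute-phase list 18 of 25 rose and none fell (18 up adjusted over the list alone, camera p = 5.16e-19, adjusted p = 0.108 with an estimated correlation). In the NF-kB list 12 of 24 rose and none fell (12 up adjusted over the list alone, camera p = 1.7e-12, adjusted p = 0.108 with an estimated correlation), with the apoptosis inhibitor gene BIRC3 at 3.78 ± 0.22 and TNFAIP2 at 3.23 ± 0.17. In the glutathione, NRF2 and ferroptosis list 8 of 21 rose and none fell (9 up adjusted over the list alone, camera p = 2.77e-08, adjusted p = 0.108 with an estimated correlation), with SLC7A11 at 1.47 ± 0.21, SLC3A2 at 2.09 ± 0.18 and TXNRD1 at 1.32 ± 0.14. Of 39 genes of the estrogen response 18 fell and 4 rose (23 and 6 adjusted over the list alone, camera p = 8.42e-10, adjusted p = 0.108 with an estimated correlation), with STC2 falling by 1.28 ± 0.12 and CXCL12 by 2.24 ± 0.16. Of 33 genes of the cell cycle 8 fell and none rose (10 down adjusted over the list alone, camera p = 1.41e-10, adjusted p = 0.485 with an estimated correlation), among them MCM4 (fell by 0.99 ± 0.15). In the p53 target list 9 of 18 rose and none fell (9 up and 1 down adjusted over the list alone, camera p = 2.07e-05, adjusted p = 0.108 with an estimated correlation), including the cyclin-dependent kinase inhibitor gene CDKN1A at 1.91 ± 0.16.

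For T47D with HS5, edgeR called 1697 of 13538 genes without the allowance (958 up, 739 down) and 1554 with it (872 up, 682 down). With the allowance the count was 200 without a batch term, 797 without T47D monoculture replicate 2 and 1011 without monoculture replicate 3.

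T47D cells from co-culture with HS27a had higher levels of sterol and fatty acid synthesis genes and lower levels of the progesterone receptor and ferroportin genes (3 against 3 biological replicates). Again the monoculture of batch 2 adds nothing to these log2 fold changes. ID1, a target of BMP signalling, rose by 2.54 ± 0.21, and its relative ID3 by 1.80 ± 0.18. DUSP6, a phosphatase gene that restrains ERK, rose by 2.01 ± 0.25. SOX2, a stem cell transcription factor gene, fell by 2.23 ± 0.19, and PGR, which encodes the progesterone receptor, fell by 1.29 ± 0.18, from 1158 ± 159 CPM to 512 ± 128 CPM. ESR1 fell by 0.75 ± 0.13. The PGR call ended without T47D monoculture replicate 2 (-1.31) or 3 (-1.28), and the ESR1 call without replicate 3 (-0.70).

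In cholesterol synthesis, 11 of 23 genes rose and none fell in T47D with HS27a (18 up adjusted over the list alone), with MVD at 1.45 ± 0.15, MVK at 0.95 ± 0.15 and DHCR7 at 0.88 ± 0.13. The camera p was 2.36e-23, and adjusted p = 0.322 with an estimated correlation. In fatty acid synthesis 3 of 13 rose and none fell (7 up adjusted over the list alone, camera p = 3.43e-08, adjusted p = 0.322 with an estimated correlation), namely FASN at 0.76 ± 0.11, SCD at 0.68 ± 0.11 and ELOVL6 at 1.05 ± 0.22, the last lost without T47D monoculture replicate 3 (0.87). Of 34 genes of the interferon response 6 fell and none rose (19 down adjusted over the list alone, camera p = 7.41e-18, adjusted p = 0.322 with an estimated correlation), among them OAS1 (fell by 1.59 ± 0.31), OAS2 (fell by 1.37 ± 0.28) and IFIT3 (fell by 1.53 ± 0.29). Its median log2 ratio was -0.45 within batch 3 and -1.26 and -1.35 in the replicates of batch 4, the calls of OAS1 (-0.79), OAS2 (-0.45) and IFIT3 (-0.60) ended without T47D monoculture replicate 3 and that of OAS2 also without co-culture replicate 3 (-1.40), and 1 library of batch 3 stood apart from the other libraries of its replicate. Of 39 genes of the estrogen response 6 fell and none rose (11 down and 2 up adjusted over the list alone, camera p = 2.27e-07, adjusted p = 0.322 with an estimated correlation), including TFF3, which fell by 1.04 ± 0.14. In the ER stress and amino acid list 9 of 26 rose and none fell (10 up adjusted over the list alone, camera p = 0.000342, adjusted p = 0.483 with an estimated correlation), with CHAC1 at 1.76 ± 0.30 and PSAT1 at 1.56 ± 0.25. In the same list the ASNS call ended without T47D monoculture replicate 2 (2.03) or co-culture replicate 1 (1.44), and the SESN2 call without co-culture replicate 1 (0.62).

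In the iron handling list of T47D with HS27a, 1 of 35 genes fell and none rose (1 up and 1 down adjusted over the list alone, camera p = 0.793, adjusted p = 0.813 with an estimated correlation). SLC40A1 fell by 0.94 ± 0.19, from 435 ± 106 CPM to 194 ± 22.6 CPM (adjusted p = 0.0245), and the call ended without T47D monoculture replicate 2 (-0.74). TFRC (-0.20 ± 0.11, adjusted p = 0.63), FTH1 (0.25 ± 0.19, adjusted p = 0.761), FTL (0.08 ± 0.14, adjusted p = 0.919) and LCN2 (3.54 ± 1.79, adjusted p = 0.656) did not pass, though LCN2 was called without co-culture replicate 3 (4.10). By edgeR, 334 genes were called without the allowance (174 up, 160 down) and 204 with it (91 up, 113 down). With the allowance the count was 0 without a batch term (655 genes at an unadjusted p under 0.05), 91 without T47D monoculture replicate 3, and 134 without co-culture replicate 1.

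The direct contrast of the stromal partners in T47D, with the allowance, called 1787 genes (990 higher with HS5, 797 higher with HS27a). CP was higher with HS5 by 8.40 ± 0.36, FGB by 8.60 ± 0.28, C3 by 6.21 ± 0.26 and BIRC3 by 3.44 ± 0.19. ID1 was lower with HS5 (-2.74 ± 0.21). That count was 70 without a batch term.

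The cancer lines were compared in 1 fit with a term for the difference in response. With HS5, 286 genes rose in both lines against 67.1 expected by chance, and 193 fell in both against 39.3 expected (the lines have separate controls). Expected counts here and below take genes as independent and equally likely to be called. Fractions of both lines held RNA of the same stromal line, so remaining partner RNA was not excluded as a source of genes that rose in both. The response differed between the lines for 506 genes (197 with the higher log2 change in MCF7, 309 in T47D), and 49 of these were called in opposite directions. TFRC differed by 0.93 ± 0.19 (MCF7 minus T47D), FTH1 by -1.61 ± 0.24 and FTL by -1.09 ± 0.21, whereas CP (-4.53 ± 1.80, adjusted p = 0.213), STEAP4 (1.59 ± 0.74, adjusted p = 0.298) and ESR1 (0.70 ± 0.20, adjusted p = 0.0513) were not shown to differ. For FTH1 the T47D side rests on single cultures of batch 3, since in batch 4 it was at 0.0 CPM in T47D monoculture and 1.74 CPM with HS5. With HS27a the response differed for 72 genes, 16 genes rose in both lines against 1.25 expected, and 12 fell in both against 1.87 expected. Without the allowance for partner RNA the HS27a count was 189.

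**Figure D3:**
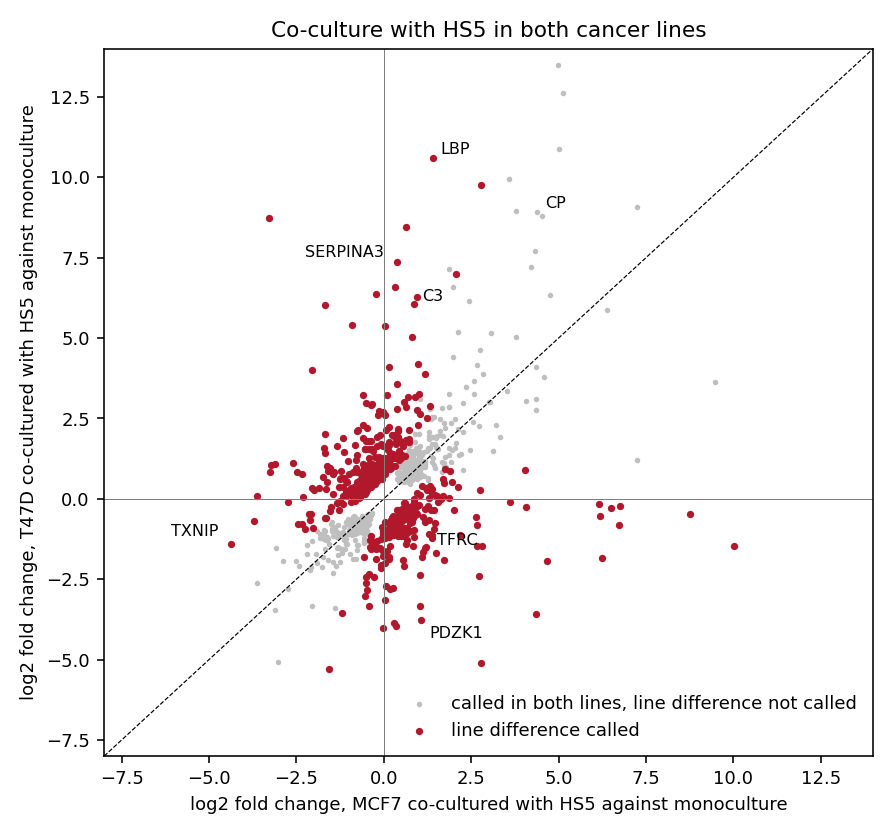
Log2 fold change after co-culture with HS5 in MCF7 (x axis) and in T47D (y axis), 1 point per gene, for the genes called in both lines or with a called difference between the lines (506, in red), and a dashed line of equal change. LBP and C3 lie above that line, TXNIP lies below 0 on both axes, and CP lies above 0 on both axes with no called difference.

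**Figure D4:**
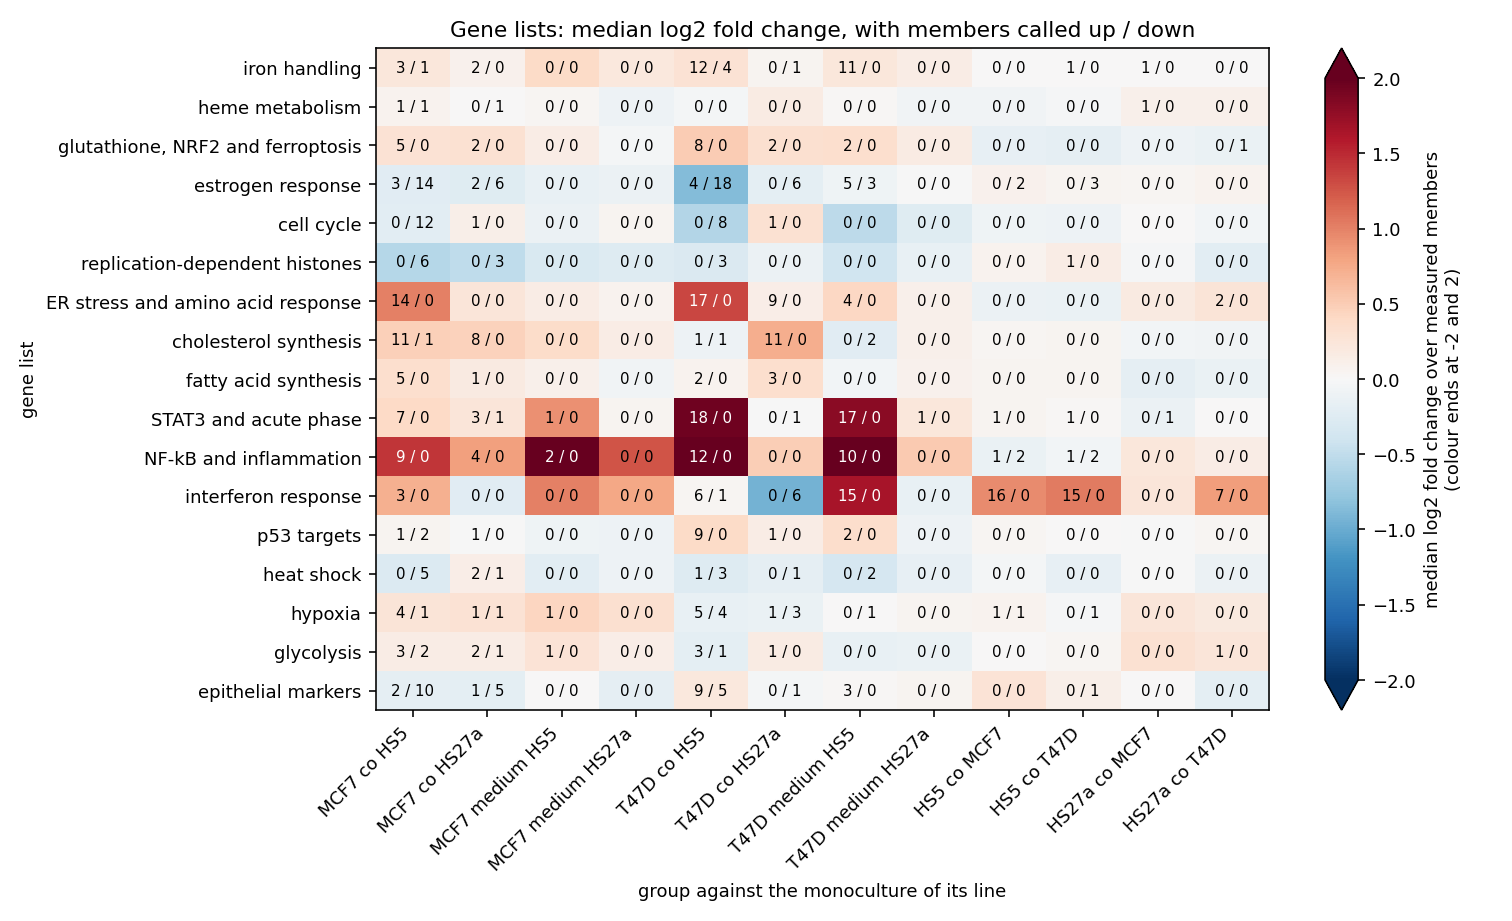
Median log2 fold change over the measured members (colour) of 17 gene lists (rows) in the 12 groups tested against the monoculture of their line (columns), with the number of members called up and down in each cell. ER stress genes show 14 and 17 calls up in MCF7 and T47D with HS5, cholesterol synthesis 11 and 8 in MCF7 and 11 in T47D with HS27a, and interferon genes 16 and 15 in HS5 after co-culture.

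Medium conditioned by HS5 was read for changes that need no contact between the cells. In T47D it raised interferon, acute-phase and iron genes (1 biological replicate against 3, so its spread was taken from the other groups of the line). The T47D monoculture of batch 2 adds nothing to these log2 fold changes either. FGB was 918 times its monoculture level (95% counting interval 254 to 7590) and C3 rose by 7.31 ± 0.33. IFITM1, which encodes an antiviral membrane protein, rose by 3.30 ± 0.24, to 525.5 CPM from 30.7 ± 27.3 CPM, and B2M, which encodes the light chain of class I molecules, rose by 1.38 ± 0.16. SPINK5, which encodes a serine protease inhibitor, fell by 2.84 ± 0.41 and ESR1 fell by 0.78 ± 0.19. Of 34 interferon genes 15 rose and none fell (24 up adjusted over the list alone, camera p = 1.85e-28, adjusted p = 0.242 with an estimated correlation). In the STAT3 and acute-phase list 17 of 25 rose and none fell (17 up adjusted over the list alone, camera p = 1.89e-28, adjusted p = 0.0586 with an estimated correlation). Of 35 genes of iron handling 11 rose and none fell (11 up adjusted over the list alone, camera p = 6e-08, adjusted p = 0.0708 with an estimated correlation), with CP at 9.15 ± 0.51, LCN2 at 10.65 ± 0.89, STEAP4 at 2.62 ± 0.34, FTH1 at 1.52 ± 0.20 and FTL at 1.11 ± 0.19. LCN2 was at 0.0 CPM in the monoculture of batch 3, so the size of its fold is poorly fixed. TFRC (-0.18 ± 0.17, adjusted p = 0.853) and SLC40A1 (0.19 ± 0.23, adjusted p = 0.898) did not pass. In all 387 genes were called (294 up, 93 down), 13 without a batch term and 239 without T47D monoculture replicate 2, which also ended the calls of LCN2 (10.29), FTH1 (5.52), ESR1 (-0.86) and IFITM1 (2.24), while the LCN2 call also ended without monoculture replicate 3 (12.96). With the replicate number of the labels as a block in place of batch, the count in HS5 medium fell further and FTH1 changed sign (-3.99). The direct contrast of co-culture and medium with HS5 in T47D called 340 genes (153 higher in co-culture, 187 lower).

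In MCF7, medium conditioned by HS5 lowered TXNIP and raised a small set of genes (1 biological replicate against 3). TXNIP fell by 2.43 ± 0.24, to 95.8 CPM from 592 ± 91.2 CPM, and S100A7A, with no counts in monoculture, was at least 37.5-fold higher. OSMR rose by 2.31 ± 0.34 and ADM, which encodes the peptide hormone adrenomedullin, by 3.58 ± 0.49. TFRC (0.42 ± 0.21, adjusted p = 0.533), FTH1 (0.60 ± 0.21, adjusted p = 0.35), LCN2 (5.07 ± 1.72, adjusted p = 0.461) and ESR1 (-0.91 ± 0.24, adjusted p = 0.232) did not pass. No iron gene of 32 passed over all genes or adjusted over the list alone, though camera with a preset correlation gave p = 0.000996 upward (adjusted p = 0.48 with an estimated correlation). The STAT3 and acute-phase list had 1 of 22 genes up over all genes and 11 adjusted over the list alone (camera p = 1.85e-12, adjusted p = 0.358 with an estimated correlation). Of 12903 genes 24 were called (18 up, 6 down), 0 without a batch term (254 at an unadjusted p under 0.05 by edgeR) and 98 by DESeq2. The count was 13, 1 and 135 without MCF7 monoculture replicates 1, 2 and 3, where leaving out replicate 2 ended the calls of S100A7A, OSMR (2.42) and ADM (3.10), and it was 304 with the replicate number of the labels as a block in place of batch. The direct contrast of co-culture and medium with HS5 in MCF7 called 69 genes (35 higher in co-culture, 34 lower).

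Medium conditioned by HS27a gave few calls. In MCF7 edgeR called 0 genes (445 at an unadjusted p under 0.05) and DESeq2 5, and the count was 44 without MCF7 monoculture replicate 3 and 327 with the label number as a block. TFRC (0.33 ± 0.21), FTH1 (0.21 ± 0.21), FTL (0.44 ± 0.30) and ESR1 (-0.32 ± 0.24) each had adjusted p = 1. In T47D, NTN4, which encodes a netrin, rose by 1.65 ± 0.32 and SERPINA3, which encodes a serine protease inhibitor, by 1.60 ± 0.30, and no other gene passed (369 at an unadjusted p under 0.05 by edgeR, 0 called by DESeq2). The NTN4 call ended without T47D monoculture replicate 1 (1.65), 2 (1.49) or 3 (1.75), and the SERPINA3 call without replicate 1 (1.60) or 2 (0.21). In all 14 genes were called without replicate 2 and 0 without replicate 1 (331 at an unadjusted p under 0.05 by edgeR). TFRC (-0.05 ± 0.17), FTH1 (0.27 ± 0.20), SLC40A1 (0.39 ± 0.22) and ESR1 (-0.29 ± 0.18) each had adjusted p = 1. The direct contrast of the media called 290 genes in T47D (241 higher with HS5, 49 lower) and 2 in MCF7 (1 higher, 1 lower). Co-culture and medium with HS27a differed in 171 genes in T47D (70 higher in co-culture, 101 lower) and 25 in MCF7 (12 higher, 13 lower).

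HS5 cells after co-culture with MCF7 gained interferon-stimulated genes (3 against 3 biological replicates). IFI44L rose by 1.66 ± 0.17, RSAD2, which encodes the antiviral enzyme viperin, by 1.85 ± 0.23, and BST2, which encodes the antiviral protein tetherin, by 2.21 ± 0.26. Without HS5 monoculture replicate 2 these calls ended (1.40, 1.49 and 2.72), as did those of IFI44L (0.93) and BST2 (0.34) without co-culture replicate 2 and that of RSAD2 (1.87) without monoculture replicate 3. NPTX1, a neuronal pentraxin gene, fell by 2.58 ± 0.37, ALDH1A3, which encodes a retinaldehyde dehydrogenase, by 1.13 ± 0.13, and SERPINB2, which encodes a plasminogen activator inhibitor, by 1.06 ± 0.10. Of 34 interferon genes 16 rose and none fell (26 up adjusted over the list alone, camera p = 4.13e-45, adjusted p = 0.57 with an estimated correlation), with a median log2 ratio of 0.36 in batch 1 and 1.22 in batch 2. No iron gene of 29 passed (0 adjusted over the list alone, camera p = 0.929, adjusted p = 0.991 with an estimated correlation), and TFRC was at 0.14 ± 0.10 (adjusted p = 0.846) and FTL at -0.23 ± 0.10 (adjusted p = 0.539). LCN2, with no counts in HS5 monoculture, was at least 39.2-fold higher before the allowance, where partner RNA made up 84.9% of its level, and did not pass with it (adjusted p = 0.329). By edgeR 151 of 11546 genes were called without the allowance (117 up, 34 down) and 92 with it (62 up, 30 down). With the allowance 0 were called with the label number as a block in place of batch (160 at an unadjusted p under 0.05), and 47, 47, 13, 38 and 154 without HS5 monoculture replicate 1, co-culture replicate 1, monoculture replicate 2, co-culture replicate 2 and co-culture replicate 3.

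HS5 cells after co-culture with T47D gained interferon-stimulated genes as well (3 against 3 biological replicates). IFI44L rose by 1.48 ± 0.16 and RSAD2 by 1.77 ± 0.23. Both calls ended without HS5 monoculture replicate 2 (1.24 and 1.42), and that of RSAD2 also without monoculture replicate 3 (1.79) or co-culture replicate 3 (1.79). NPTX1 fell by 2.46 ± 0.33, SHISA2 by 2.12 ± 0.31 and ALDH1A3 by 1.36 ± 0.13. Of 34 interferon genes 15 rose and none fell (26 up adjusted over the list alone, camera p = 1.71e-57, adjusted p = 0.668 with an estimated correlation), with a median log2 ratio of 0.89 in batch 2 and 0.76 in batch 4. In the iron handling list 1 of 29 rose and none fell (1 up and 1 down adjusted over the list alone, camera p = 0.635, adjusted p = 0.91 with an estimated correlation). That gene was LCN2, with no counts in HS5 monoculture and at least 6.15-fold higher, whose call ended without HS5 monoculture replicate 2 (9.18) or without co-culture replicate 1 (5.26). Of its 30 counts, 28 were in the co-culture of batch 2 (4.28 CPM), which has no T47D fraction, so the allowance used T47D monoculture there. At the LCN2 level of co-cultured T47D in the other batches (530.3 and 2459.2 CPM), the T47D share of 1.192% would bring 6.32 to 29.31 CPM, so the call is no evidence of a rise in HS5 cells. TFRC (0.18 ± 0.10, adjusted p = 0.721), FTH1 (0.21 ± 0.13, adjusted p = 0.77) and FTL (-0.13 ± 0.10, adjusted p = 0.848) did not pass. By edgeR 109 genes were called without the allowance (69 up, 40 down) and 101 with it (61 up, 40 down). With the allowance 0 were called with the label number as a block in place of batch (279 at an unadjusted p under 0.05), and 66, 25 and 63 without HS5 monoculture replicates 1, 2 and 3 and 157 and 62 without co-culture replicates 1 and 3.

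HS27a cells after co-culture with MCF7 showed few called genes (3 against 3 biological replicates). DHRS3, which encodes a retinaldehyde reductase, fell by 1.19 ± 0.13, from 121 ± 18.1 CPM to 49.6 ± 5.24 CPM. HMOX1, which encodes the heme-degrading enzyme heme oxygenase, rose by 1.21 ± 0.23, and its call ended without HS27a monoculture replicate 2 (0.50) or co-culture replicate 2 (0.50). HMOX1 was the gene called of 29 in the iron handling list (1 up adjusted over the list alone, camera p = 0.167, adjusted p = 0.566 with an estimated correlation), while TFRC (0.12 ± 0.10, adjusted p = 0.954), FTH1 (0.33 ± 0.12, adjusted p = 0.544) and SLC40A1 (0.24 ± 0.21, adjusted p = 0.952) did not pass. Of 19 glycolysis genes none passed over all genes and 9 rose adjusted over the list alone (camera p = 2.15e-13, adjusted p = 0.196 with an estimated correlation). By edgeR 39 of 11111 genes were called without the allowance (21 up, 18 down) and 23 with it (10 up, 13 down). With the allowance 0 were called with the label number as a block (92 at an unadjusted p under 0.05), and 9, 9, 62 and 58 without HS27a monoculture replicate 1, co-culture replicate 1, co-culture replicate 3 and monoculture replicate 3.

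HS27a cells after co-culture with T47D gained interferon genes (3 against 3 biological replicates). MX1, which encodes an antiviral GTPase, rose by 2.24 ± 0.27, from 7.75 ± 7.71 CPM to 87.5 ± 45.3 CPM, and ISG15, a ubiquitin-like modifier gene, by 1.55 ± 0.25. Both calls ended without HS27a monoculture replicate 3 (1.09 and 0.63), and that of ISG15 also without co-culture replicate 2 (1.49) or 3 (1.48). CYP1B1, which encodes an estrogen-metabolising enzyme, fell by 1.31 ± 0.12, from 920 ± 46.3 CPM to 370 ± 82.7 CPM. Of 32 interferon genes 7 rose and none fell (19 up adjusted over the list alone, camera p = 2.67e-37, adjusted p = 0.155 with an estimated correlation), with median log2 ratios of 1.19 and 1.04 in the replicates of batch 4, the 1 batch with both groups. No iron gene of 29 passed (0 adjusted over the list alone, camera p = 0.752, adjusted p = 0.863 with an estimated correlation), and TFRC was at 0.06 ± 0.12 (adjusted p = 0.969) and SLC40A1 at 0.34 ± 0.26 (adjusted p = 0.868). By edgeR 14 genes were called without the allowance (8 up, 6 down) and 24 with it (16 up, 8 down). With the allowance the count was 0 without a batch term (319 at an unadjusted p under 0.05), and 186, 3 and 5 without co-culture replicate 1, HS27a monoculture replicate 3 and co-culture replicate 2.

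**Figure D5:**
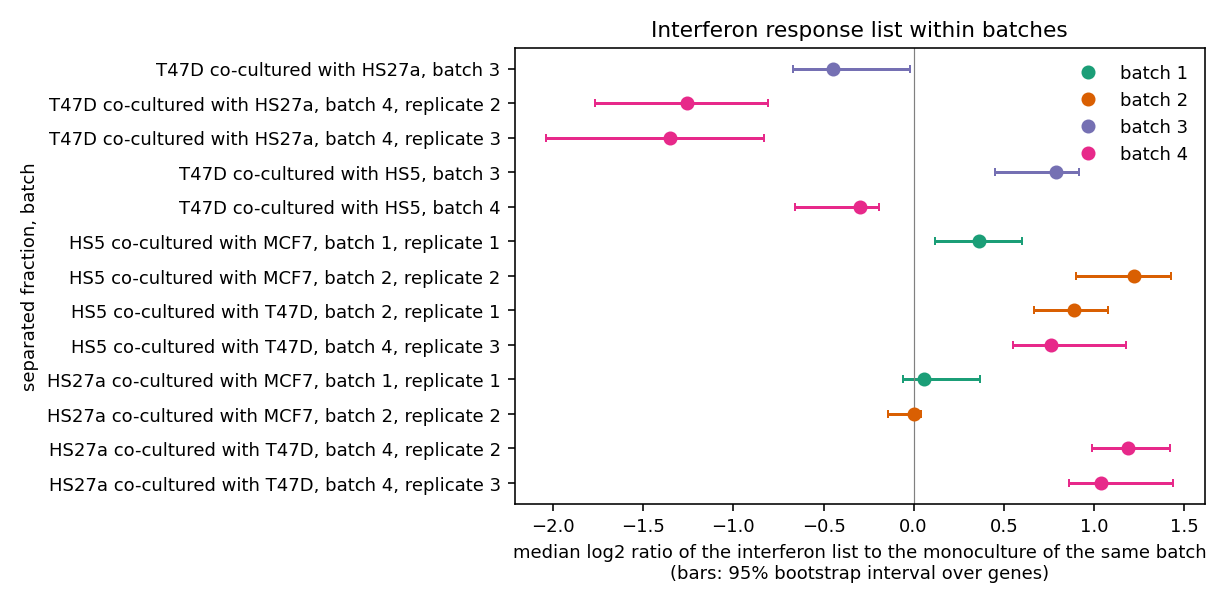
Median log2 ratio of the interferon response list to the monoculture of the same batch (x axis) in each co-cultured replicate whose batch holds that monoculture (y axis), with 95% bootstrap intervals over genes, coloured by batch. T47D with HS27a lies at -0.45, -1.26 and -1.35, T47D with HS5 at 0.79 in batch 3 and -0.30 in batch 4, HS5 between 0.36 and 1.22, HS27a with T47D at 1.19 and 1.04, and HS27a with MCF7 at 0.06 and 0.0.

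The stromal monocultures were compared as the background to the co-cultures, and HS5 expressed inflammatory genes where HS27a expressed matrix genes (3 against 3 biological replicates). IL6, which encodes an inflammatory cytokine, was higher in HS5 by 7.77 ± 0.39 (1426 ± 1447 CPM against 6.93 ± 7.39 CPM), and PTGS2, which encodes a prostaglandin synthase, by 7.19 ± 0.56. CSF3, a growth factor gene for granulocytes with no counts in HS27a, was at least 2760-fold higher. POSTN, which encodes the matrix protein periostin, was lower in HS5 (-12.68 ± 0.64), and so were the collagen gene COL6A3 (-11.55 ± 0.45) and the chemokine gene CXCL12 (-8.88 ± 0.43). PIEZO2, a mechanosensitive channel gene with no counts in HS5, was at least 1080-fold lower. Of 25 NF-kB genes 20 were higher and 1 lower (20 and 1 adjusted over the list alone, camera p = 1.59e-24, adjusted p = 0.186 with an estimated correlation), while of 26 matrix genes 17 were lower and 2 higher (17 and 2 adjusted over the list alone, camera p = 2.17e-15, adjusted p = 0.186 with an estimated correlation). Of 77 ribosomal protein genes 41 were higher in HS5 and 1 lower (59 and 1 adjusted over the list alone, camera p = 6.43e-11, adjusted p = 0.722 with an estimated correlation).

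In iron handling 8 of 27 genes were higher in HS5 than in HS27a and 2 lower (8 and 2 adjusted over the list alone, camera p = 0.00991, adjusted p = 0.442 with an estimated correlation). SLC25A37 was higher by 2.18 ± 0.22, SLC39A14, which encodes a zinc and iron importer, by 2.04 ± 0.26, and STEAP3, which encodes the endosomal ferrireductase, by 2.15 ± 0.34. FBXL5, which encodes an iron-sensing ubiquitin ligase subunit, was lower (-1.18 ± 0.23), and its call ended without HS5 monoculture replicate 2 (-1.34) or 3 (-1.06) or HS27a monoculture replicate 2 (-1.36). Among the other called iron genes, ACO1, NCOA4, SLC11A2 and STEAP2 also lost their calls when a single replicate was left out. TFRC (-0.01 ± 0.20, adjusted p = 0.98), FTH1 (0.83 ± 0.30, adjusted p = 0.0835) and FTL (0.40 ± 0.30, adjusted p = 0.37) did not pass. By edgeR 2759 of 10295 genes were called (1308 higher in HS5, 1451 lower), and 1324 without a batch term. The count was 714 and 1732 without HS5 monoculture replicates 2 and 3, and 749 and 1748 without HS27a monoculture replicates 2 and 3.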

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

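All tests of causes in this part were chosen after the result was seen, while the comparison of the cancer lines was planned. The test of dilution was divided by batch after its values were seen.

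The responses of MCF7 and T47D differed by a test of the difference itself for 506 genes in co-culture with HS5, for 72 with HS27a and for 20 in medium conditioned by HS5. Values below are the log2 fold change in MCF7 minus that in T47D. The genes below were named because their difference was called, so they stand for no group of genes. With HS5 the values were negative for LBP (-9.21), SERPINA3 (-6.97), CHI3L2 (-6.97), C3 (-5.17), ICAM1 (-4.22), RELB (-2.27), CEBPD (-1.81) and NFKBIA (-1.40), whereas other acute-phase and STAT3 genes were not shown to differ (adjusted p = 0.337 for SAA1, 0.437 for SAA2, 0.324 for LCN2, 0.556 for CEBPB and 0.0866 for OSMR). They were also negative for TXNIP (-2.97), KRT18 (-2.15), KRT8 (-0.95), CDKN1A (-1.52), RAB31 (-1.24) and TXNRD1 (-0.75). Among the iron genes named above for these co-cultures, they were negative for FTH1 (-1.61, in T47D from batch 3 alone), SLC25A37 (-1.16), FTL (-1.09) and NCOA4 (-0.89), and positive for TFRC (0.93). They were positive for PDZK1 (4.82), SPINK5 (4.16), GPR132 (4.00), LRRN3 (3.73), STC2 (1.18) and MCM6 (0.90), and for the sterol genes MVD (1.08), HMGCS1 (1.06) and DHCR24 (0.87). With HS27a they were CRH (-5.05), ID4 (-3.41), BNIPL (-2.34), MT1F (-2.30), RAB31 (-0.86), CYP26A1 (7.07), SOX2 (2.98), SYBU (2.04) and TUBB2B (1.90). In medium of HS5 they were SERPINA3 (-6.55) and C3 (-4.85).

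Of 20 tests in 12 groups for a library far from the others, 5 were past the limit, in 4 groups. Chance flags about 1 in 20 groups of independent samples, and libraries of the same biological replicate are not independent, so that rate need not hold here. These were the total counts of HS5 from co-culture with MCF7 (5088444.0, batch 3) and the partner share of HS5 from co-culture with MCF7 (0.0%, batch 3), MCF7 from co-culture with HS27a (0.266%, batch 3), HS27a from co-culture with MCF7 (0.0%, batch 3) and T47D from co-culture with HS5 (3.24%, batch 4). Mitochondrial rRNA, which no comparison used, made up 5.41% of counts in T47D from co-culture with HS5 and 4.95% and 5.43% in T47D from co-culture with HS27a in batch 4, against 4.03% in the monoculture of that batch.

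Genes rose in MCF7 with HS5 in batches 1 and 2, where HS5 RNA made up 17.3% to 24.9%. If HS5 RNA were the whole cause, the 609 genes still called with the allowance would be at their monoculture level in batch 3, where the share was 0.820%. Their median log2 ratio there was 0.9 (0.81 to 0.97), and 92.2% of 588 genes read were higher. These genes were chosen for exceeding the allowance, so those that HS5 RNA lifts above its median share can exceed it again in batch 3. In HS5 medium, without HS5 cells in the culture, the median of the 609 genes was 0.39 (0.35 to 0.46), with 81.7% of 551 read higher. Together these values argue against HS5 RNA as the whole cause for the set, but 0.9 is no measure free of HS5 RNA. For the 1075 genes called only without the allowance the median in batch 3 was 0.32 (0.27 to 0.37), and 70.1% of 790 read were higher. Genes at a very low level in both samples were not read, which favours genes that remaining HS5 RNA lifts. This median therefore cannot exclude HS5 RNA as their whole cause. In HS5 medium their median was 0.14 (0.11 to 0.19), with 61.8% of 718 read higher. How much of their rise in batches 1 and 2 it made up was not measured. A response of MCF7 to the partner stays open, as does a difference in seeding density, which the labels do not give for monocultures and which was not tested. The labels give both the same medium.

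FTH1 and other genes were near 0 in batch 4 and not elsewhere (114 of 5897 genes over 50 CPM elsewhere). The median share of exonic bases that overlap another gene was 36.5% (28.8% to 41.2%) for these and 0.0% for the others, so reads left unassigned in such exons are a candidate explanation. Reads counted on FTH1 pseudogenes in its place were argued against, since those reached at most 150.0 CPM in batch 4 while FTH1 had 306.3 to 3539.3 CPM in batch 3. No biological explanation was tested.

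Interferon genes were lower in T47D with HS27a, with median log2 ratios of -1.26 and -1.35 in batch 4. In batch 3 the median was -0.45 (-0.67 to -0.02, 23 of 29 genes lower) against monoculture. Against HS27a medium it was -0.56 (-0.84 to -0.37, 26 of 30 lower). Both medians were at percentile 0.0 of random lists matched on level. That percentile treats the genes of a list as independent and holds no spread between cultures. It therefore cannot decide whether these medians exceed chance differences between cultures. Without the batch 4 monoculture, the mean of the list changed by -0.42 in a model of all T47D groups. That value rests on the batch 3 monoculture alone, since batch 2 held no other T47D group. Its spread holds none between monocultures, so it cannot decide on a high level in the batch 4 monoculture as the cause. The lower level within batch 3 does not involve that monoculture, but it was read against single cultures. The part of that monoculture in the larger fall of batch 4 stays open. With all cultures and the spread between them, the change was -0.95 (-1.93 to 0.04). T47D with HS5 was at -0.30 in batch 4 against 0.79 in batch 3. The batch 3 library that stood apart, letter B, was lowered least (-0.25, against -0.48 and -0.39 in letters A and C), which argues against that library as the cause of the batch 3 fall. Without it and the batch 4 monoculture the change was -0.46, which again rests on the batch 3 monoculture alone. Dilution by HS27a RNA can lower a gene by at most -0.033 in batch 4 and -0.008 in batch 3, which argues against it. An effect of HS27a on interferon signalling may remain.

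Splits of the same samples into groups of equal size number 10 per comparison (9 for HS27a with T47D, where 1 split could not be fitted), and in each 1 split, the real one, gave as many genes. These splits are too few for a share under 0.05. Without the allowance the real count and the highest other were 2772 and 0 for MCF7 with HS5, 944 and 17 for MCF7 with HS27a, 334 and 32 for T47D with HS27a, 151 and 60 for HS5 with MCF7, 39 and 9 for HS27a with MCF7, 109 and 11 for HS5 with T47D, 14 and 12 for HS27a with T47D, and 2759 and 0 for HS5 against HS27a. With it they were 2049 and 0, 667 and 0, 204 and 38, 92 and 48, 23 and 7, 101 and 5, and 24 and 18, in the same order.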

How the results depend on the processing

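The counts with batch 3 alone, with letter B left out and for the differences between partners and between lines under other settings were chosen after the data were seen. A number in brackets after 0 is the count of genes at an unadjusted p under 0.05 by the same tool. For each count below that moved by more than 1.5 times, the cause was not tested unless stated.

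Without a batch term the count of genes was 481 for MCF7 with HS5 (with the allowance 161), 9 for MCF7 with HS27a (with the allowance 3), 237 for T47D with HS5 (with the allowance 200) and 0 (771) for T47D with HS27a (with the allowance 0 (655)). It was 0 (254) for MCF7 in HS5 medium, 13 for T47D in HS5 medium, 0 (22) for T47D in HS27a medium and 0 (83) for HS5 with MCF7 (with the allowance 0 (44)). It was 0 (77) for HS27a with MCF7 (with the allowance 0 (48)), 0 (75) for HS5 with T47D (with the allowance 0 (73)), 0 (322) for HS27a with T47D (with the allowance 0 (319)) and 1324 for HS5 against HS27a. It was 2 for partners in MCF7 and 70 for partners in T47D.

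With every library as a replicate, which treats repeated libraries as independent, each test has more samples by construction. The count was 5610 for MCF7 with HS5 (with the allowance 4339), 3214 for MCF7 with HS27a (with the allowance 2402), 317 for T47D with HS27a with the allowance and 2176 for MCF7 in HS5 medium. It was 354 for MCF7 in HS27a medium, 712 for T47D in HS5 medium, 1 for T47D in HS27a medium and 526 for HS5 with MCF7 (with the allowance 352). It was 483 for HS27a with MCF7 (with the allowance 334), 396 for HS5 with T47D (with the allowance 372), 88 for HS27a with T47D (with the allowance 89) and 6315 for HS5 against HS27a. It was 2566 for partners in MCF7, 3001 for partners in T47D, 1313 for lines with HS5 and 225 for lines in HS5 medium. It was 390 for lines with HS27a and 1 for lines in HS27a medium.

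With no filter on low counts the count was 1226 for MCF7 with HS27a with the allowance, 314 for T47D with HS27a with the allowance, 70 for MCF7 in HS5 medium and 4 for MCF7 in HS27a medium. It was 312 for HS5 with MCF7 (with the allowance 147), 208 for HS27a with MCF7 (with the allowance 62), 194 for HS5 with T47D (with the allowance 166) and 88 for HS27a with T47D (with the allowance 72). It was 1034 for partners in MCF7, 800 for lines with HS5, 87 for lines in HS5 medium and 235 for lines with HS27a. It was 1 for lines in HS27a medium. With DESeq2 size factors it was 14 for MCF7 in HS5 medium. With no allowance for partner RNA it was 6 for lines in HS5 medium and 189 for lines with HS27a.

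The label number was not shown to pair samples across batches. With it as the replicate block in place of batch the count was 282 for T47D with HS5 (with the allowance 218), 4 for T47D with HS27a (with the allowance 0 (878)), 304 for MCF7 in HS5 medium and 327 for MCF7 in HS27a medium. It was 5 for T47D in HS5 medium, 0 (143) for T47D in HS27a medium, 0 (232) for HS5 with MCF7 (with the allowance 0 (160)) and 0 (140) for HS27a with MCF7 (with the allowance 0 (92)). It was 0 (266) for HS5 with T47D (with the allowance 0 (279)), 2 for HS27a with T47D (with the allowance 2) and 38 for partners in T47D. With that block these called genes changed sign: FTH1 in T47D with HS5 (-4.43), ASNS in T47D with HS27a (-0.22), RELB in MCF7 in HS5 medium (-0.04), TNFAIP3 in MCF7 in HS5 medium (-0.48), FTH1 in T47D in HS5 medium (-3.99), SERPINA3 in T47D in HS27a medium (-2.04).

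With the DESeq2 test the count was 1053 for T47D with HS5, 181 for T47D with HS27a, 98 for MCF7 in HS5 medium and 5 for MCF7 in HS27a medium. It was 212 for T47D in HS5 medium, 0 (104) for T47D in HS27a medium, 50 for HS5 with MCF7 and 15 for HS27a with MCF7. It was 32 for HS5 with T47D and 8 for HS27a with T47D. With limma voom it was 1884 for MCF7 with HS27a, 501 for MCF7 in HS5 medium, 38 for MCF7 in HS27a medium and 694 for T47D in HS5 medium. It was 0 (705) for T47D in HS27a medium, 119 for HS27a with MCF7, 169 for HS5 with T47D and 25 for HS27a with T47D. In batch 3 alone each group is 1 biological replicate, some with 1 library, and the spread comes only from repeated libraries of the same replicate, so these counts are set against technical noise and support no result. There it was 1557 for MCF7 with HS5, 466 for MCF7 with HS27a, 1032 for T47D with HS5 and 119 for T47D with HS27a. It was 773 for MCF7 in HS5 medium, 11 for MCF7 in HS27a medium and 0 (277) for T47D in HS27a medium. Without letter B it was 0 (307) for T47D in HS27a medium.

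With each replicate left out in turn the count was 1468 to 2633 for MCF7 with HS5 (with the allowance 1100 to 2421), 321 to 1100 for MCF7 with HS27a (with the allowance 168 to 635), 952 to 1748 for T47D with HS5 (with the allowance 797 to 1557), 123 to 314 for T47D with HS27a (with the allowance 91 to 195). It was 1 to 135 for MCF7 in HS5 medium, 0 to 44 for MCF7 in HS27a medium, 239 to 347 for T47D in HS5 medium, 0 to 14 for T47D in HS27a medium. It was 33 to 254 for HS5 with MCF7 (with the allowance 13 to 154), 15 to 212 for HS27a with MCF7 (with the allowance 9 to 62), 20 to 103 for HS5 with T47D (with the allowance 25 to 157), 10 to 121 for HS27a with T47D (with the allowance 3 to 186). It was 714 to 4052 for HS5 against HS27a. Leaving out T47D monoculture replicate 1, the only T47D sample of batch 2, removes nothing that a T47D log2 fold change rests on.

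With an estimated correlation camera called 0 lists in each comparison, against 18 in MCF7 with HS5, 14 in MCF7 with HS27a, 10 in T47D with HS5, 14 in T47D with HS27a, 13 in MCF7 in HS5 medium, 8 in MCF7 in HS27a medium, 11 in T47D in HS5 medium, 3 in T47D in HS27a medium, 4 in HS5 with MCF7, 14 in HS27a with MCF7, 3 in HS5 with T47D, 13 in HS27a with T47D, 12 in HS5 against HS27a with the preset correlation.

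Of 284 called values of named genes, 198 lost their call without a batch term, 133 with the label number as a block (6 with a changed sign), 5 with DESeq2 size factors and 0 with no filter, where 5 others gained one. With 1.5 times the partner share 3 of 207 lost their call. Leaving out 1 replicate ended the call in 236 of 1521 refits of called values and gave 5 new ones, and 0 changed sign. Of the called named genes, those that kept their call whichever replicate was left out numbered 40 of 50 in MCF7 with HS5, 9 of 26 in MCF7 with HS27a, 49 of 53 in T47D with HS5, 15 of 36 in T47D with HS27a, 1 of 12 in MCF7 in HS5 medium, 21 of 29 in T47D in HS5 medium, 0 of 2 in T47D in HS27a medium, 3 of 14 in HS5 with MCF7, 1 of 7 in HS27a with MCF7, 4 of 13 in HS5 with T47D, 1 of 8 in HS27a with T47D, 27 of 34 in HS5 against HS27a.

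Depth limits genes near the floor of 3 counts over a group, such as SLC40A1 in MCF7, where no fold is given for co-culture with HS5.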

Other observations

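The lists in this part were chosen beforehand, the split of the interferon list by batch after its result was seen, and no test of a cause was run for them. In co-cultured cancer cells, 6 of 11 genes for factors of mesenchymal transition rose in MCF7 with HS5 and none fell (8 up adjusted over the list alone, camera p = 0.00654, adjusted p = 0.383 with an estimated correlation). HS5 RNA made up 17.3% to 24.9% of these fractions in batches 1 and 2, VIM went from 0.584 to 950 CPM, 7 of 28 stromal markers also rose with the allowance, and the list had 10 calls up without it, so a change in the MCF7 cells themselves was not shown. Of 18 genes for growth factor receptors 2 rose and 4 fell there (7 up and 4 down adjusted over the list alone, camera p = 0.684, adjusted p = 0.891 with an estimated correlation). Of 7 metallothionein and metal response genes 2 rose in T47D with HS27a and none fell (2 up adjusted over the list alone, camera p = 0.00142, adjusted p = 0.322 with an estimated correlation). The MT1F call ended without T47D monoculture replicate 2 (1.76) or 3 (1.89) or co-culture replicate 1 (1.74), and the MT2A call without monoculture replicate 2 (0.30) or co-culture replicate 1 (0.55) or 2 (0.58). Of 15 heat shock genes 5 fell in MCF7 with HS5 and none rose (5 down adjusted over the list alone, camera p = 0.00273, adjusted p = 0.383 with an estimated correlation). Of 19 histone genes 6 fell there and none rose (6 down adjusted over the list alone, camera p = 5.19e-05, adjusted p = 0.341 with an estimated correlation).

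Heme metabolism had 1 gene up and 1 down of 17 in MCF7 with HS5 (1 and 1 adjusted over the list alone, camera p = 0.399, adjusted p = 0.599 with an estimated correlation). Of 30 nuclear genes of oxidative phosphorylation 1 fell in T47D with HS5 and none rose (1 down adjusted over the list alone, camera p = 0.00955, adjusted p = 0.602 with an estimated correlation). In HS27a with T47D, 1 of 19 TGF-beta, YAP and contractile genes rose and none fell (6 up adjusted over the list alone, camera p = 8.37e-07, adjusted p = 0.286 with an estimated correlation). In HS5 against HS27a, 11 of them were lower and 1 higher (11 and 1 adjusted over the list alone, camera p = 2.7e-06, adjusted p = 0.523 with an estimated correlation). The interferon list in T47D with HS5 had a median log2 ratio of 0.79 in batch 3 and -0.30 in batch 4.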
